A study of Homo sapiens with 35 samples.

How the data were processed

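Extracellular vesicles were isolated from the plasma of healthy controls and of people with non-severe or severe asthma, and their small RNA was sequenced, one library per subject. Per the labels' protocols, vesicle RNA was purified with a Norgen kit and libraries were made with the QIAseq miRNA kit, which uses unique dual indexes. FastQC, DESeq2 and the genome build hg38 are named in the submitters' processing notes. The aligner, the miRNA annotation, the counting rule and whether reads were collapsed by molecular identifier are not given in the sources used here.

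The deposited table gives 854 mature miRNAs in 35 columns as a normalized signal, which the series' design text ties to a DESeq2 analysis by the authors. In every column the deposited values were whole multiples of one step, so that each column was a set of read counts divided by one size factor. Dividing by that step gave whole reads for 100% of the values above 0, within 0.001 read. Size factors recomputed from these reads by the median-of-ratios rule differed from the recovered ones by at most 0.035 (log2). The total of recovered reads per library is the number of reads assigned to miRNAs, not the number sequenced.

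Columns were matched to subjects by the number in their names. Of the 35 columns, 2 were not used, because the number of one stands in 2 sample titles and that of the other in none. The 33 used columns were 14 healthy controls, 10 people with non-severe asthma and 9 with severe asthma, against 15, 10 and 10 in the labels. Every library came from a different subject, so p-values rest on the spread between libraries. Differences between people cannot be separated in it from those of library preparation and depth. No pair of libraries held identical values, and correlations between libraries over log2 values ran from 0.77 to 0.98. Some miRNAs with the same or nearly the same mature sequence had identical or almost identical rows. Values of miR-517a-3p and miR-517b-3p, of miR-199a-3p and miR-199b-3p, of miR-1268a and miR-1268b, and of the single members of the let-7 family are therefore uncertain as to which member they came from.

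Values were tested as log2(value + 1), so a fold change is on that scale. For a miRNA with few reads it depends on the added value and can lie below or above that of a count model. For miR-330-3p in severe asthma against controls it was 2.17, and 2.77 or 0.98 with 0.5 or 5 added instead. The count models edgeR and DESeq2 gave 1.66 and 1.71. Subjects counted above a group's mean of a miRNA were those above the mean of its log2 values. A miRNA was kept if its value was at least 5 in at least 10 libraries, which left 349 of the 854, with 99.9% of the summed values. The main test was limma-trend (limma 3.58.1 in R 4.3.3, robust) with all 3 groups in one fit, a contrast for each of the 3 pairs of groups and a moderated F test over all groups. P-values were adjusted by the Benjamini-Hochberg rule within a comparison, with a threshold of 0.05 and no minimum fold. All tests were two-sided, except that the p-value of an area under the ROC curve was the share of shuffles with an area at least as high.

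The following choices were made before the data were examined. They were the groups, the test, the filter, 16 lists of miRNAs, the rule for which miRNAs are named, and a set of alternative settings. The lists held markers of erythroid cells, platelets, myeloid leukocytes, lymphocytes, liver, muscle, epithelium, neural tissue, endothelium and smooth muscle, miRNAs linked to inflammation, the let-7, miR-17-92 and miR-29/30 families, and the imprinted DLK1-DIO3 and placental C19MC clusters. A list's score in a subject was the mean, over its kept members, of log2(value + 1) less that miRNA's mean over all libraries. Scores were compared by a permutation test of 100000 resamples, or by the exact permutation test where a group had fewer than 10 subjects, and adjusted over the lists. The naming rule took the 10 miRNAs with the smallest unadjusted p in a comparison where fewer than 10 passed, plus miR-451a and miR-23a-3p. The rule gave 26 different miRNAs. Any other member of a list given as an example was chosen after its values were seen.

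A haemolysis index, log2 of (miR-451a + 1) over (miR-23a-3p + 1), was taken as a measure of red-cell RNA. The number of miRNAs above 0 and the share of the 10 highest miRNAs described each library. Separation of groups was measured as the area under the ROC curve in 5-fold cross-validation, repeated 20 times, with 10 miRNAs chosen inside each training fold and 99 shuffles of the labels. Correlations between the contrasts that share the healthy controls were set beside those of 100 random regroupings of the libraries into groups of the same sizes. Each count of miRNAs past the threshold was recomputed for 100 splits of the libraries into groups of the same sizes, the real split included.

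Alternatives covered the pseudocount (0.5 and 5), the filter (none, or a mean of at least 50), scaling to a common total, quantile normalization, sample quality weights, the haemolysis index as a covariate, a fit of only the groups compared, a threshold of 0.1, an exact rank-sum test per miRNA, and count models on the recovered reads. The count models were the quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0. Camera, with a preset correlation of 0.01 or an estimated one, was run beside the list scores. Alternatives chosen after the data were seen were log2 depth or sample numbering as covariates, fits within the lower-numbered and the higher-numbered libraries, fits without the 4 libraries under 400000 reads or without the shallowest one, fits without the 1 or 2 non-severe libraries highest for miR-1-3p or with each library left out in turn, and rarefaction to 300000 reads. Scaling to a common total moved the median fold change of all kept miRNAs to 0.31 (log2) for non-severe asthma and 0.36 for severe asthma against controls, from 0.10 and 0.13 with the deposited scaling.

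Other computations used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions of miRNA genes came from GENCODE release 29 on GRCh38, where 34 of the 35 miRNAs looked up by name were matched. An exon location means that some annotated transcript of the host gene has an exon there, while other transcripts may have an intron. The limma step was tested on simulated reads, drawn 3 times from the real means and depths with known folds. At 4-fold it called 82.2% of changed miRNAs for non-severe asthma against controls, 80.6% for severe asthma against controls and 75.6% for severe against non-severe asthma, over means of 347, 344 and 343 miRNAs tested. At 2-fold it called 33.0%, 26.5% and 21.4%, and of unchanged miRNAs 0.37%, 1.58% and 0.39%. Over the 3 draws the tested miRNAs were 118, 134 and 123 changed 4-fold, 115, 136 and 126 changed 2-fold, and 808, 761 and 779 unchanged. Each miRNA was drawn independently of the others. With so many changed, the adjusted threshold is easier to pass, so these shares do not give the chance of calling a single changed miRNA. The list score called 6 of 6 simulated lists shifted by 1.0 (log2), 3 of 6 shifted by 0.5 and 0 of 6 with no shift.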

Results

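Small RNA was sequenced from extracellular vesicles, the membrane-bound particles that cells release into blood plasma, to look for miRNAs that mark the severity of asthma. The libraries compared came from 14 healthy controls, 10 people with non-severe asthma and 9 people with severe asthma. Reads assigned to miRNAs ranged from 116509 to 4893028 per library, with a median of 949829. They averaged 843470 ± 412116 (SD) in controls, 1371813 ± 736461 in non-severe asthma and 1608757 ± 1569960 in severe asthma. On the log2 scale depth was 0.74 higher in non-severe asthma than in controls (permutation p = 0.0700, adjusted p = 0.210), and 0.63 higher in severe asthma (exact permutation p = 0.206, adjusted p = 0.309).

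The vesicle miRNAs were dominated by the let-7 family, regulators of growth and differentiation that are abundant in most mature tissues. As mean shares of the normalised counts over the 33 libraries, let-7a-5p held 21.2% ± 4.30 (SD), let-7f-5p 10.4% ± 2.69, let-7b-5p 8.36% ± 2.59, let-7g-5p 6.58% ± 1.24 and let-7i-5p 4.84% ± 1.12. Between them stood miR-16-5p, abundant in red cells, at 8.08% ± 2.997, miR-126-3p, encoded in an intron of the endothelial gene EGFL7, at 7.35% ± 2.74, and miR-26a-5p at 6.35% ± 2.21. The liver miRNA miR-122-5p reached 1.19% ± 2.33 and the red-cell miRNA miR-486-5p 1.12% ± 0.74. The let-7 family together took 56.9% ± 8.55 in controls, 51.4% ± 7.82 in non-severe asthma and 51.7% ± 8.02 in severe asthma. These shares did not differ beyond the spread between subjects, with a permutation adjusted p of 0.239 for either asthma group against controls and 0.925 between the asthma groups. The 10 highest miRNAs of a library held 81.3% ± 3.54, 78.6% ± 3.10 and 78.3% ± 3.13 of its normalised counts in the same order (permutation adjusted p = 0.0945, 0.0945 and 0.842).

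More miRNAs had at least a read in non-severe asthma (539 ± 81.1) than in controls (460 ± 70.6), a difference of 78.5 (SE 31.8, permutation p = 0.0165, adjusted p = 0.0495). In severe asthma the number was 538 ± 119, and its difference of 77.9 from controls missed the threshold (exact permutation p = 0.0619, adjusted p = 0.0928). The number followed depth, with Pearson r = 0.86 and Spearman rho = 0.81 over 33 libraries (permutation p = 1e-05 for both, the smallest that 100000 resamples can give, adjusted p = 0.0001 over 10 relations), and r was 0.83 without the 2 libraries farthest from the median depth. Within groups r was 0.75 in controls (rho 0.54), 0.85 in non-severe asthma (rho 0.88) and 0.93 in severe asthma (rho 0.95). Without the 2 farthest libraries of each group r was 0.36, 0.74 and 0.99, so that the strength of the relation within controls rested on 2 libraries. Counted at a normalised value of 5 or more, which a single read exceeded in the shallowest library, the numbers were 315 ± 14.7, 322 ± 18.6 and 319 ± 14.7, and the difference of non-severe asthma from controls was 6.94 (permutation adjusted p = 0.665). At an equal 300000 reads per library it was 29.1 (SE 14.03, permutation p = 0.0605, adjusted p = 0.181), with 1 control too shallow to enter. Without that control library, of 116509 reads, and with no other change, the difference was 65.4 (SE 29.5) and did not pass (permutation p = 0.0280, adjusted p = 0.0840). Among the libraries of at least 400000 reads, which leave it out as well, the difference was 72.2 (SE 29.5) and passed (exact permutation p = 0.0154, adjusted p = 0.0462). With each of the 33 libraries left out in turn the difference ran from 60.7 to 90.4 and passed 15 times.

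**Figure D1:**
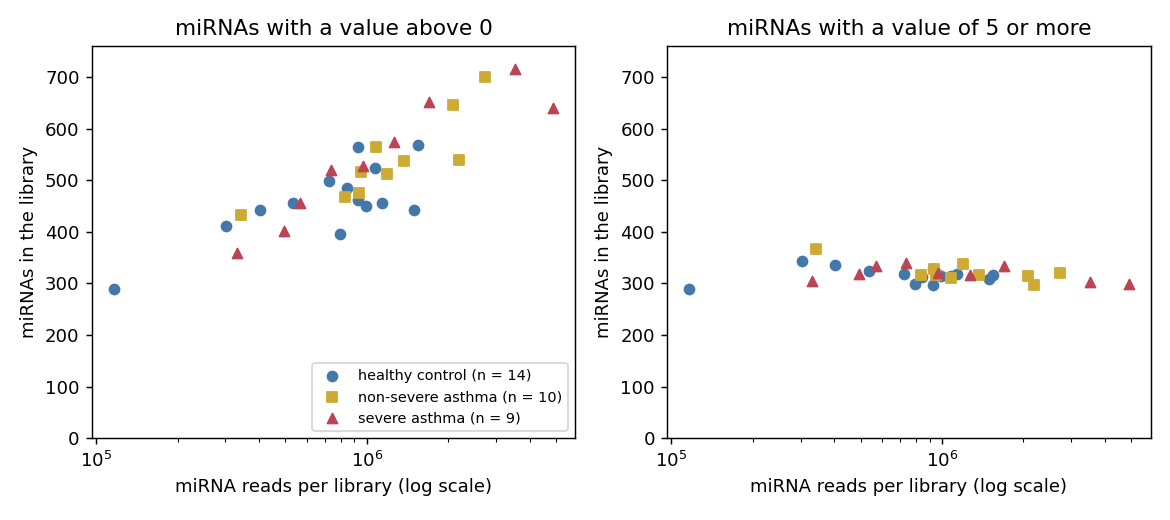
Number of miRNAs per library (y axis) against miRNA reads per library (x axis, log scale), for miRNAs with a value above 0 (left) and of 5 or more (right); each point is a library and its shape and colour give the group. Above 0 the number climbs with depth in each group (r = 0.86 over all 33 libraries), while at 5 or more the libraries lie between 290 and 366.

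Differences in the haemolysis index, a measure of red-cell RNA, the usual contaminant of plasma miRNA, did not pass in any comparison. The index was 0.83 ± 1.003 (SD) in controls, 0.46 ± 0.99 in non-severe asthma and 0.24 ± 1.31 in severe asthma. The differences were −0.37 for non-severe asthma against controls (SE 0.41, permutation adjusted p = 0.557), −0.59 for severe asthma against controls (SE 0.51, exact permutation adjusted p = 0.557) and −0.22 between the asthma groups (SE 0.54, exact permutation adjusted p = 0.688). Mean normalised counts of miR-451a, a miRNA of maturing red cells, were 2417 ± 1452, 2519 ± 1703 and 2432 ± 2035, and those of miR-23a-3p, the denominator of the index, 1175 ± 370, 1496 ± 389 and 1540 ± 230. In non-severe and severe asthma against controls the log2 fold changes were −0.0036 and −0.15 for miR-451a, and 0.37 and 0.44 for miR-23a-3p. The lower index in asthma thus came mostly from its denominator and cannot be read as less red-cell RNA. The direction of the small miR-451a differences changed with the scaling.

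The comparison of non-severe asthma with healthy controls asked which vesicle miRNAs mark the milder disease. No miRNA passed the threshold. The 10 with the smallest unadjusted p included a miRNA of muscle, a miRNA of the erythroid list and 2 of the imprinted DLK1-DIO3 cluster on chromosome 14. The muscle miRNA miR-1-3p averaged 931 ± 1646 normalised counts (SD, n = 10) against 152 ± 154.1 in controls (n = 14). Its log2 fold change was 1.496 (SE 0.56, limma adjusted p = 0.837), with 8 of 10 subjects above the control mean of log2 values. The mean of 931 rested on 2 libraries: the median was 171, and without the highest library the mean was 514 and the log2 fold change 1.05 (SE 0.51). Without the 2 highest they were 167 ± 72.4 (SD, n = 8) and 0.56 (SE 0.44). Its genes lie on chromosome 20 at 62554306 to 62554376 and on chromosome 18 at 21829004 to 21829088. For miR-96-5p, of a cluster known from sensory cells and placed on the erythroid list, the log2 fold change was 1.46 (SE 0.56, 9 of 10 subjects above the control mean). It had few reads, with none in 8 of 14 controls and medians of 0 reads in controls and 6.5 in non-severe asthma. The DLK1-DIO3 members miR-487b-3p and miR-654-3p had log2 fold changes of 1.45 (SE 0.66) and 1.16 (SE 0.53), each with 9 of 10 subjects above the control mean. Their control medians were 3.5 and 7.5 reads.

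The remaining miRNAs of that set were miR-584-5p at a log2 fold change of 1.26, miR-548au-5p at 1.23, miR-330-3p at 1.17, miR-224-5p at 1.10 (0.72 without the shallowest control library), miR-23a-3p at 0.37 and miR-454-3p at −0.70. All 10 had a limma adjusted p of 0.837. Folds of miR-584-5p, miR-548au-5p and miR-330-3p rested on few reads, with control medians of 3, 2 and 0. With limma 0 of 349 miRNAs passed, and 11 had an unadjusted p under 0.05, 10 of them higher in asthma, where 17.45 would come by chance. The counts past the threshold were also 0 with edgeR (16 unadjusted), DESeq2 (19) and the exact rank-sum test (10). With each library left out in turn edgeR called 1 miRNA in 5 of 33 fits and DESeq2 1 in 2 of 33.

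None of the 16 lists passed in this comparison (smallest adjusted p = 0.506), and with limma 0 members of any list passed, adjusted over the list alone or over all miRNAs tested. The muscle list was 0.79 (log2, SE 0.40) higher in non-severe asthma (permutation p = 0.0633, adjusted p = 0.506), with 9 of 10 subjects above the control mean and all 5 kept members fitted above 0. Besides miR-1-3p these included miR-133a-3p at 0.998, miR-499a-5p at 0.98 and miR-206 at 0.36. Within the lower-numbered libraries the muscle difference was 1.5 and within the higher-numbered ones 0.085. The 2 non-severe libraries highest for miR-1-3p, both lower-numbered, had muscle scores of 2.53 and 1.83. The other non-severe libraries lay between −0.30 and 0.44. A dependence on the numbering can therefore not be told apart from these 2 libraries. Platelet miRNAs were 0.31 (SE 0.13) higher (permutation p = 0.0423, adjusted p = 0.506), with 14 of 16 kept members fitted above 0, among them miR-199a-5p at 0.91 and miR-223-3p at 0.50, which is abundant in myeloid cells as well. Of the DLK1-DIO3 cluster 23 of 25 kept members were fitted above 0, at a list difference of 0.48 (SE 0.49, permutation p = 0.345). In the let-7 list 9 of 11 kept members were fitted below 0, at a list difference of −0.20 (SE 0.17, permutation p = 0.247), which became 0.03 when libraries were scaled to a common total. With camera's preset correlation the platelet and DLK1-DIO3 lists were called higher and the let-7 list lower (adjusted p = 0.0189, 0.0213 and 0.00107). With an estimated correlation the adjusted p values were 0.443, 0.722 and 0.443.

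The other lists had permutation p values of 0.145 (smooth muscle) or more. The differences were 0.20 for myeloid leukocytes, 0.19 for smooth muscle, 0.18 for erythroid cells, 0.09 for inflammation, 0.09 for the miR-17-92 family, 0.07 for neural tissue, 0.04 for the miR-29/30 family and 0.03 for endothelium. Those below 0 were −0.02 for lymphocytes, −0.16 for liver, −0.16 for epithelium and −0.54 for C19MC. Scaled to a common total, lymphocytes stood at 0.20, liver at 0.06 and epithelium at 0.01, and after quantile normalization the miR-29/30 family stood at −0.02. The median of the members had the other sign than their mean for erythroid cells (−0.0068) and endothelium (−0.05).

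The comparison of severe asthma with healthy controls asked which miRNAs mark the more severe disease. Vesicle miR-330-3p was higher in severe asthma, at a mean of 8.30 ± 2.50 normalised counts (SD, n = 9) against 2.21 ± 3.34 (n = 14) in controls. In non-severe asthma it averaged 4.69 ± 3.88 (n = 10). Its log2 fold change in severe asthma against controls was 2.17 (SE 0.51, 95% interval 1.15 to 3.20, limma adjusted p = 0.0398), and all 9 subjects with severe asthma lay above the control mean. It had no read in 9 of 14 controls, in 1 of 10 people with non-severe asthma and in none with severe asthma, and its median was 0 reads in controls, 4 in non-severe asthma and 12 in severe asthma. The gene of miR-330 lies on chromosome 19 at 45638994 to 45639087 (GRCh38, minus strand), in an exon of some annotated transcript of EML2, which codes for a microtubule-binding protein.

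The call rested on few reads and stayed past the threshold in 5 of 19 alternative settings (log2 fold change 0.98 to 2.77) and in 16 of 33 fits that each left out 1 library (2.10 to 2.35). It ended with edgeR (log2 fold change 1.66, adjusted p = 0.350), DESeq2 (1.71, adjusted p = 0.225) or depth as a covariate (2.01, adjusted p = 0.134). It also ended with the part of the numbering, lower or higher, as a covariate (2.09, adjusted p = 0.0631) and without the shallowest control library (2.10, adjusted p = 0.0738). Among the libraries of at least 400000 reads it stayed past the threshold (2.35, adjusted p = 0.0333).

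The remaining 9 miRNAs of the severe set did not pass (limma adjusted p = 0.370 for each). miR-224-5p, from within GABRE on chromosome X (151958578 to 151958658), averaged 105 ± 91.3 against 39.2 ± 18.5 in controls. Its log2 fold change was 1.29 (SE 0.50), with 8 of 9 subjects above the control mean, and 0.90 without the shallowest control library. miR-7977 stood at 1.27 (SE 0.51, 8 of 9 above), with medians of only 0.5 reads in controls and 7 in severe asthma. Lower values belonged to the immune miRNAs miR-155-5p, induced when lymphocytes and macrophages are activated (exon of MIR155HG, chromosome 21, 25573980 to 25574044), at −0.76 (SE 0.30), and miR-342-3p, abundant in lymphocytes (intron of EVL, chromosome 14, 100109655 to 100109753), at −0.67 (SE 0.26), each with 1 of 9 subjects above the control mean. let-7g-5p, from an intron of WDR82 on chromosome 3 (52268278 to 52268361), had a log2 fold change of −0.61 (SE 0.22), miR-31-5p −1.26 (SE 0.47) and miR-1294 −0.95 (SE 0.38), each with 2 of 9 subjects above. miR-3960 stood at −1.74 (SE 0.58) and miR-1268a at −1.41 (SE 0.54), each with 1 of 9 above. Both had few reads, with medians of 8.5 and 5.5 in controls and 4 and 5 in severe asthma. For miR-23a-3p of the haemolysis index the value was 0.44 (SE 0.18, adjusted p = 0.370, 9 of 9 above) and for miR-451a −0.15 (SE 0.42, adjusted p = 0.891, 4 of 9 above). With limma 1 miRNA passed and 40 had an unadjusted p under 0.05, 20 in each direction. edgeR called 0 (39 unadjusted), the exact rank-sum test 0 (32) and DESeq2 1 (44), which was miR-224-5p at a log2 fold change of 1.41 (adjusted p = 0.0463). DESeq2 called it in 13 of 33 fits that each left out 1 library, and the DESeq2 count of miRNAs ran from 0 to 12 over these fits.

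**Figure D2:**
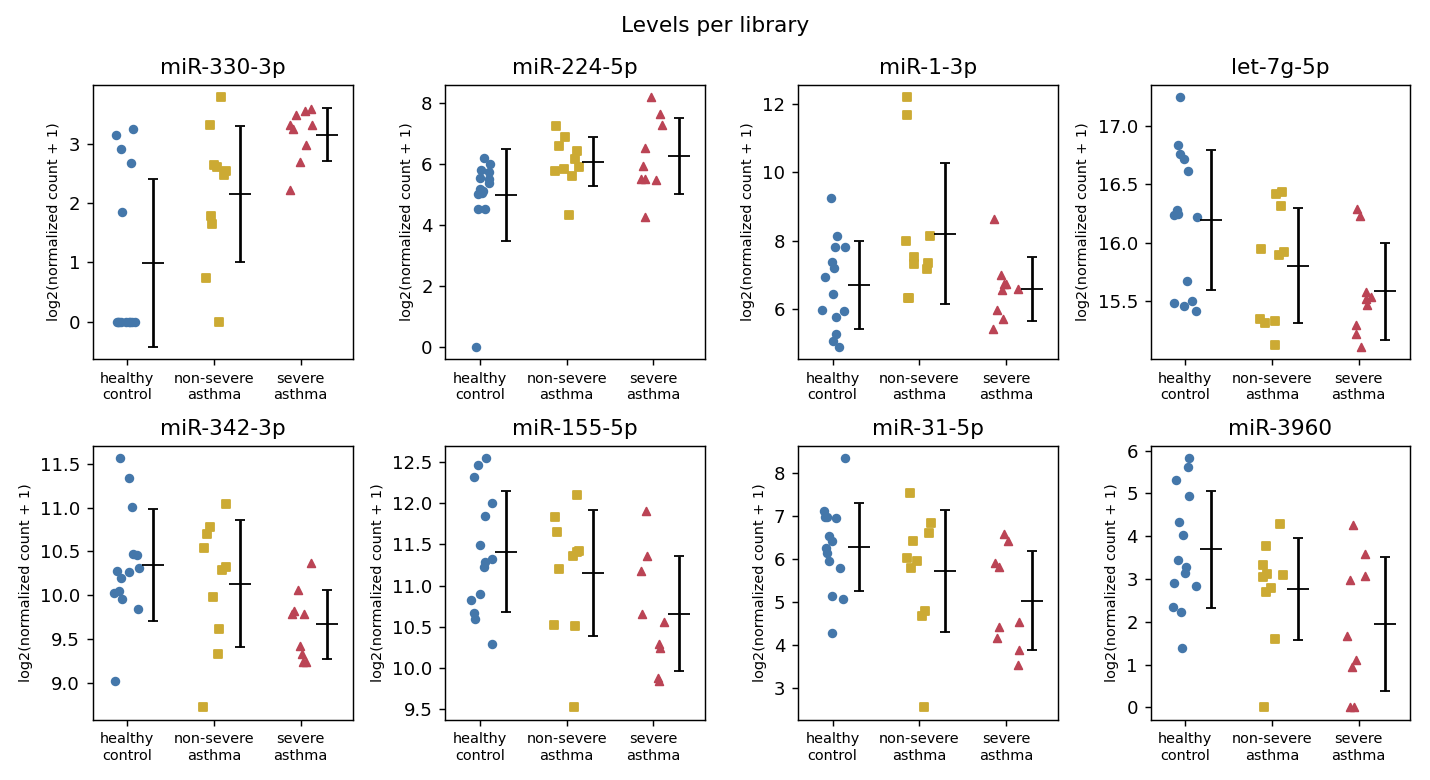
Levels of 8 named miRNAs per library, as log2(normalised count + 1) on y axes that differ between panels and do not all start at 0; points are libraries of healthy controls (n = 14), non-severe asthma (n = 10) and severe asthma (n = 9), and bars give the mean ± SD. miR-330-3p is at 0 in 9 of 14 controls and above 0 in every library of severe asthma, and the groups overlap in all 8 panels.

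Markers of blood cells did not pass as lists in severe asthma against controls, and with limma 0 members of any list passed, adjusted over the list alone or over all miRNAs tested. With sample quality weights 5 members passed over all miRNAs tested: miR-223-3p at 0.96, miR-199a-3p at 0.80, miR-150-5p at −1.17, miR-155-5p at −0.94 and miR-31-5p at −1.48. Platelet miRNAs were 0.31 (SE 0.16) higher (exact permutation p = 0.0745, adjusted p = 0.289), with 4 of 16 members higher at an unadjusted p under 0.05, among them miR-199a-3p at 0.56, which shares its sequence with miR-199b-3p, and miR-328-3p at 1.07. Myeloid leukocyte miRNAs were 0.29 (SE 0.14) higher (exact permutation p = 0.0594, adjusted p = 0.289), with 3 of 11 members higher at that level, including miR-223-3p at 0.64 and miR-338-3p at 1.09. Lymphocyte miRNAs were −0.29 (SE 0.16) apart (exact permutation p = 0.0739, adjusted p = 0.289), and 4 of 12 members were lower at that level. These were miR-342-3p, miR-155-5p, miR-150-5p at −0.93 and miR-342-5p at −0.84. In the let-7 list 10 of 11 members were fitted below 0, at a list difference of −0.29 (SE 0.16, exact permutation p = 0.0904, adjusted p = 0.289), which was −0.02 when libraries were scaled to a common total. The lymphocyte difference was then −0.04.

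Neural miRNAs, 3 kept, were 0.40 (SE 0.18) higher in severe asthma (exact permutation p = 0.0580, adjusted p = 0.289). All 25 kept DLK1-DIO3 members were fitted above 0, at a list difference of 0.57 (SE 0.44, exact permutation p = 0.244, adjusted p = 0.558), with miR-376c-3p at 0.94 and miR-154-5p at 1.16. C19MC, whose 3 kept members include miR-517a-3p and miR-517b-3p with identical values, stood at −0.78 (SE 0.57, exact permutation p = 0.140). The other lists had exact permutation p values of 0.367 (epithelium) or more. Their differences were 0.10 for inflammation, 0.10 for smooth muscle and 0.05 for muscle, then −0.01 for endothelium, −0.03 for the miR-17-92 family, −0.12 for the miR-29/30 family, −0.13 for erythroid cells, −0.28 for liver and −0.37 for epithelium. Scaled to a common total, endothelium stood at 0.26, the miR-17-92 family at 0.21, the miR-29/30 family at 0.15 and erythroid cells at 0.11, and after quantile normalization endothelium stood at 0.05. With camera's preset correlation the platelet, DLK1-DIO3, let-7 and lymphocyte lists were called (adjusted p = 0.0288, 0.0102, 0.00749 and 0.0288). With an estimated correlation the adjusted p values were 0.582, 0.707, 0.582 and 0.582.

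**Figure D3:**
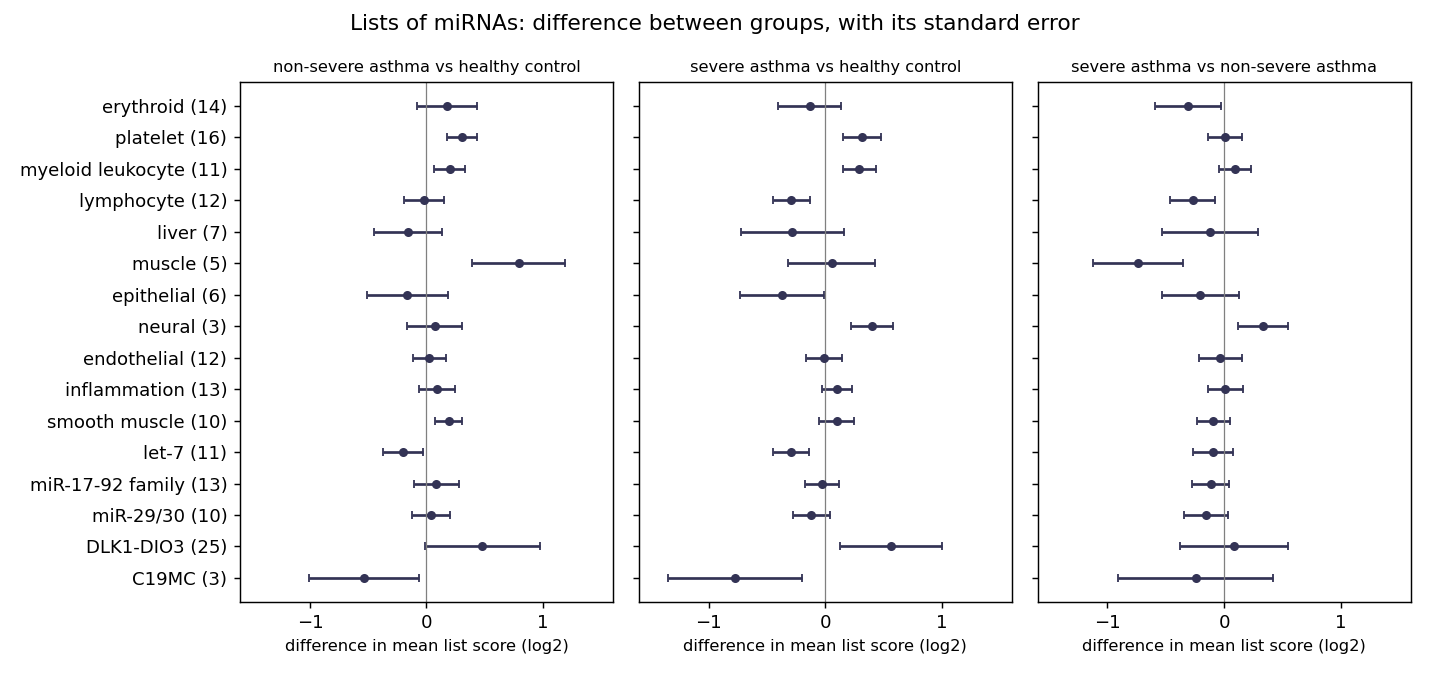
Difference in mean list score between groups (x axis, log2; points) with its standard error (bars) for each of 16 lists of miRNAs, the number of kept members in brackets, in the 3 comparisons. Muscle lies at 0.79 in non-severe asthma against controls and at −0.74 in severe against non-severe asthma, and no list passed the adjusted threshold. For muscle, 2 non-severe libraries score 2.53 and 1.83, and the other non-severe ones at most 0.44.

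The comparison of severe with non-severe asthma asked which miRNAs follow severity among people with asthma. No miRNA passed. miR-1-3p averaged 120 ± 108 normalised counts (SD, n = 9) against 931 ± 1646 (n = 10). Its log2 fold change was −1.61 (SE 0.62, limma adjusted p = 0.997), with 1 of 9 subjects above the non-severe mean of log2 values. The log2 fold change was −1.16 (SE 0.56) without the highest non-severe library and −0.67 (SE 0.48) without the 2 highest. miR-1270 stood at −1.68 (SE 0.56, 0 of 9 above), and miR-183-5p, from the same cluster as miR-96-5p, at −1.02 (SE 0.53, 3 of 9 above). On the other side miR-625-3p had a log2 fold change of 1.12 (SE 0.44), the brain miRNA miR-9-3p 1.18 (SE 0.58) and miR-641 0.96 (SE 0.49), each with 8 of 9 subjects above, and miR-330-3p 1.004 (SE 0.55, 9 of 9 above). Reads were few for miR-1270, with medians of 12.5 in non-severe and 3 in severe asthma. For miR-9-3p the medians were 4 and 7, for miR-625-3p 10.5 and 20, and for miR-641 8 and 23.

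The set was completed by miR-1268a at −1.50, its near-identical relative miR-1268b at −1.18 and miR-10399-5p at −1.42, each with 1 of 9 subjects above. Median reads of miR-1268a and of miR-1268b were 12 in non-severe and 5 in severe asthma. Those of miR-10399-5p were 11.5 and 4. The limma adjusted p was 0.997 for every miRNA named here, as it was for miR-451a at −0.15 (SE 0.45) and miR-23a-3p at 0.07 (SE 0.20). With limma 0 miRNAs passed and 7 had an unadjusted p under 0.05, 2 higher and 5 lower in severe asthma. The counts past the threshold were also 0 with edgeR (15 unadjusted), DESeq2 (12) and the exact rank-sum test (9). With each library left out in turn DESeq2 called 1 miRNA in 1 of 33 fits and edgeR 0 in all.

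No list passed between the asthma groups (smallest adjusted p = 0.941), with 0 members past the threshold with limma, adjusted over the list alone or over all miRNAs tested. The muscle list was −0.74 (SE 0.39) apart (exact permutation p = 0.0756, adjusted p = 0.941), all 5 kept members being fitted below 0. It stood at −1.68 within the lower-numbered libraries and −0.10 within the higher-numbered ones. The lower-numbered ones hold the 2 non-severe libraries with the highest muscle scores, 2.53 and 1.83. The erythroid list stood at −0.31 (SE 0.28), the lymphocyte list at −0.27 (SE 0.19) and the neural list at 0.33 (SE 0.22), with exact permutation p values of 0.292, 0.189 and 0.154. The remaining 12 lists lay between −0.24 and 0.09. Among these endothelium, at −0.03, was 0.0006 when scaled to a common total and 0.02 after quantile normalization, and platelets had a mean of 0.0082 with a member median of −0.03.

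Over all 3 groups the moderated F test called 0 miRNAs with limma (15 unadjusted, smallest adjusted p = 0.157, for miR-330-3p), 0 with DESeq2 (31 unadjusted) and 1 with edgeR (26 unadjusted). The last was miR-1-3p (adjusted p = 0.0236), and without its highest non-severe library edgeR called 0 (adjusted p of miR-1-3p = 0.536). It was called in 29 of the 33 fits that each left out 1 library. Separation of the groups in cross-validation stayed close to that of shuffled labels. The area under the curve was 0.42 for non-severe asthma against controls (one-sided permutation p = 0.63, shuffled mean 0.48), 0.57 for severe asthma against controls (one-sided permutation p = 0.28, shuffled mean 0.47) and 0.49 for severe against non-severe asthma (one-sided permutation p = 0.49, shuffled mean 0.49).

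Fold changes of the 2 asthma groups against the same controls had a Pearson r of 0.66 and a Spearman rho of 0.68 across 349 miRNAs, which are not independent replicates. Random regroupings of the same libraries, set against shared controls, gave a mean r of 0.40 (0.11 to 0.70). Of 100 regroupings 4 gave an r as large as the observed value. The covariance was 0.160 against a mean of 0.0883 over the regroupings, and 9 of 100 were as large. With the controls split between the contrasts r averaged 0.20 over 100 random splits (−0.11 to 0.37), against 0.05 over regroupings, and 26 of 100 regroupings were as large. Each regrouping was split only once. This count therefore sets an average beside single splits and cannot decide whether the 2 contrasts share changes.

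Libraries also differed along the order of the sample numbers in the labels, whose meaning the labels do not give. The let-7 share was lower at higher numbers, with Pearson r = −0.61 (permutation p = 0.00021) and Spearman rho = −0.60 (permutation p = 0.0003) over 33 libraries, adjusted p = 0.00042 and 0.00075 over 10 relations, and r was −0.58 without the 2 libraries farthest from the median number. Within groups r was −0.69 in controls (permutation p = 0.0074), −0.88 in non-severe asthma (permutation p = 0.00085) and −0.25 in severe asthma (exact permutation p = 0.50035). Without the 2 farthest libraries of each group r was −0.60, −0.78 and −0.45. The share was 59.5% ± 6.89 (SD) in the 15 lower-numbered libraries and 49.1% ± 6.38 in the 18 higher-numbered ones. Controls divided 7 and 7 between these parts, non-severe asthma 5 and 5, and severe asthma 3 and 6. The haemolysis index was higher at higher numbers (r = 0.50, permutation p = 0.00318; rho = 0.40, permutation p = 0.0218; adjusted p = 0.0053 and 0.0364), with r = 0.40 without the 2 farthest libraries. Within controls, non-severe and severe asthma r was 0.28, 0.73 and 0.74 (rho 0.15, 0.64 and 0.50). Without the 2 farthest libraries of each group r was 0.05, 0.50 and 0.35, so that the relation within groups was weaker without those libraries.

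**Figure D4:**
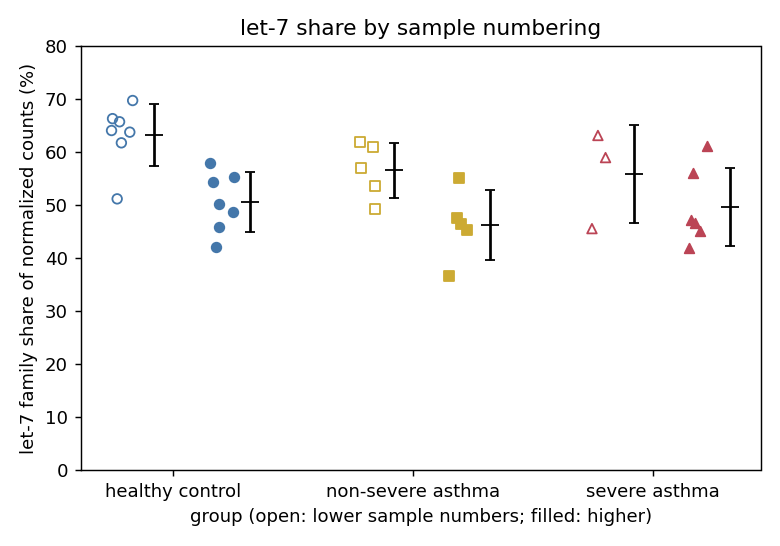
Share of the normalised counts held by the let-7 family (y axis, %) by group (x axis) in lower-numbered (open symbols) and higher-numbered (filled symbols) libraries; points are libraries and bars give the mean ± SD. In controls the mean is 63.2% at lower and 50.6% at higher numbers, in non-severe asthma 56.5% and 46.2%, and in severe asthma 55.9% and 49.6%.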

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

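The rule for a library that stands apart was fixed before any value was seen, and the list of 94 sets of values it was run on followed from the named miRNAs. In groups of 9 or 10 libraries 3 of the 94 sets had a library whose distance from its nearest neighbour took an unusually large part of the group's range, where about 1 in 20 would do so by chance, so this number is no more than chance gives. In severe asthma the highest library for miR-1-3p stood at 8.64 (log2(value + 1)), with the next at 6.998 and a group mean of 6.59 ± 0.93 (SD). The lowest library of severe asthma for miR-7977 stood at 0, with the next at 1.65 and a group mean of 2.28 ± 0.96. In non-severe asthma the lowest library for miR-10399-5p stood at 0, with the next at 2.14 and a group mean of 2.88 ± 1.29.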

How the results depend on the processing

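Settings chosen only after the data were seen were depth and numbering as covariates, the fits within parts of the numbering, the fits without shallow libraries or without the non-severe libraries highest for miR-1-3p, those with each library left out in turn, and rarefaction; the rest were planned. The cause of a change was not tested unless a setting's construction shows it. For severe asthma against controls the count past the threshold was 1. It became 0 with a pseudocount of 5, no filter (more miRNAs tested), a mean of at least 50 (which removes miR-330-3p), scaling to a common total, edgeR, the exact rank-sum test, a fit of the 2 groups alone, depth, numbering or both as covariates, edgeR with numbering, the higher-numbered libraries alone (fewer libraries), and without the shallowest library. It became 8 with sample quality weights (higher miR-330-3p, miR-223-3p, miR-199a-3p and miR-199b-3p; lower miR-150-5p, miR-155-5p, miR-31-5p and miR-3960) and 2 with the haemolysis index as a covariate (miR-330-3p and miR-4750-5p at −1.77). It was 1 in 6 of 21 alternatives, one of them a threshold of 0.1, which any call at 0.05 passes, but with DESeq2 and in the lower-numbered libraries alone the miRNA was miR-224-5p. For non-severe asthma against controls and for severe against non-severe asthma the count was 0 in all 21 alternatives (3 to 43 and 1 to 31 unadjusted), and the F test gave 1 with edgeR (0 without the highest non-severe library for miR-1-3p) and 0 in the other 16. With each library left out in turn limma gave 0 to 1 for severe asthma against controls (1 in 16 of 33 fits) and for the F test (1 in 2 fits), and 0 for the other comparisons, while edgeR gave 1 for non-severe asthma against controls in 5 fits and DESeq2 0 to 12 for severe asthma against controls. Lists past the threshold numbered 3 and 4 with camera's preset correlation in non-severe and severe asthma against controls and 0 otherwise. The difference in detected miRNAs of non-severe asthma fell from 78.5 to 6.94 at values of 5 or more to 29.1 at 300000 reads and to 65.4 without the shallowest library, none of which passed, and was 72.2, which passed, in libraries of at least 400000 reads. There severe asthma passed as well, at 82.1 above controls (exact permutation adjusted p = 0.0474), and severe against non-severe asthma turned from −0.578 to 9.96. With each library left out in turn these 3 differences ran from 60.7 to 90.4, from 55.7 to 100.3 (past the threshold in 2 of 33) and from −22.8 to 21.8. The area under the curve of severe against non-severe asthma was 0.535 with 5 miRNAs per fold, on the other side of 0.5 from the 0.49 reported. Apart from leaving out single libraries, of the values of named miRNAs 684 kept their direction and side of the threshold, 5 passed it only in the alternative, 14 no longer passed it and 15 changed sign.

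All 15 of these changes of sign were in the haemolysis pair, reported at −0.15 to 0.07. The index is built from both miRNAs, so their values with the index as a covariate follow from its construction and test nothing. miR-451a in non-severe asthma against controls, reported at −0.0036, was 0.23 scaled to a common total, 0.35 with the haemolysis index, 0.073 with edgeR, 0.056 with DESeq2, 0.24 with depth, 0.11 with depth and numbering, 0.10 in higher-numbered libraries and 0.047 with edgeR and numbering. In severe asthma against controls, reported at −0.15, it was 0.12 scaled to a common total, 0.40 with the index, 0.0049 with DESeq2 and 0.054 with depth. Between the asthma groups, reported at −0.15, it was 0.075 after quantile normalization and 0.054 with the index. miR-23a-3p between the asthma groups, reported at 0.07, was −0.065 in higher-numbered libraries. With each library left out in turn miR-451a ran from −0.18 to 0.21, from −0.41 to 0.16 and from −0.40 to 0.16 in these comparisons, and no other named miRNA changed sign. No paired analysis was possible because each library came from a different subject. Depth limits the miRNAs with few reads, among them miR-330-3p, whose absence from a shallow library cannot be told from a low level.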

Other observations

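The fits of asthma of either severity and of a slope over the groups, the split by sample numbers, the depth of rarefaction, the removal of shallow libraries and of those highest for miR-1-3p, the fits with each library left out in turn, and the tests of the 3 patterns described last were all chosen after the result they bear on, or a close relative of it, had been seen; the counts over splits of the libraries for the designed comparisons were read after the real counts, and those for the 2 added fits before.

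With both asthma groups set together against controls no miRNA passed (limma, 37 unadjusted, smallest adjusted p = 0.156), and with each library left out in turn miR-330-3p passed in 3 of 33 fits. The smallest p belonged to miR-330-3p, with a log2 fold change of 1.64 (SE 0.43, 95% interval 0.77 to 2.51), above the control mean in 17 of 19 people with asthma. Next came miR-224-5p at 1.19 (SE 0.41, 17 of 19 above), miR-3960 at −1.31 (SE 0.48, 3 of 19 above), miR-23a-3p at 0.40 (SE 0.15, 18 of 19 above), let-7g-5p at −0.49 (SE 0.18, 5 of 19 above) and miR-654-3p at 1.09 (SE 0.45, 16 of 19 above), with adjusted p = 0.450. With the groups taken in order of severity miR-330-3p alone passed, at a slope of 1.09 (log2 per step, SE 0.25, adjusted p = 0.0274). The slope also passed with the part of the numbering, lower or higher, as a covariate (adjusted p = 0.0418) and did not with depth (adjusted p = 0.109). With each library left out in turn it passed in 18 of 33 fits. The slope was the only one of these 2 added fits to make a call.

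The liver miRNA miR-122-5p averaged 16832 ± 31528 normalised counts (SD, n = 14) in controls, 6811 ± 3227 (n = 10) in non-severe asthma and 8488 ± 8771 (n = 9) in severe asthma, with log2 fold changes of −0.26 (SE 0.59) and −0.63 (SE 0.61). miR-126-3p had log2 fold changes of −0.04 (SE 0.19) in non-severe and −0.08 (SE 0.20) in severe asthma against controls. The first principal component of the kept miRNAs held 23.3% of the variance and followed log2 depth (r = 0.67, permutation p = 4e-05; rho = 0.59, permutation p = 0.00052; r = 0.50 without the 2 farthest libraries; within controls, non-severe and severe asthma 0.48, 0.69 and 0.83, and 0.19, 0.52 and 0.89 without the 2 farthest of each group). The second held 12.3% and followed the sample numbers (r = 0.66, permutation p = 6e-05; rho = 0.66, permutation p = 9e-05; r = 0.61 without the 2 farthest; within the same groups 0.63, 0.92 and 0.43, and 0.54, 0.92 and 0.43 without the 2 farthest of each).

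Chance could not be excluded for the number of miRNAs past the threshold in severe asthma against controls, where 5 of 100 splits of the libraries gave as many as the real 1 and the highest other split gave 26. That split stood alone, with 95 of the 100 at 0, and may point to a structure of the libraries, such as miRNAs that vary together whatever the group, which was not tested. The real count was 0, so that 100 of 100 splits gave as many whatever the data and nothing is decided, for non-severe asthma against controls (highest other 5), severe against non-severe asthma (highest other 11), the F test (highest other 20) and both asthma groups against controls (highest other 11). For miRNAs at an unadjusted p under 0.05, 58 of 100 splits gave as many as the real 11 in non-severe asthma against controls (highest other 62), 12 as many as 40 in severe asthma against controls (98), 62 as many as 7 between the asthma groups (91), 48 as many as 15 in the F test (94), 14 as many as 37 with both asthma groups together (87) and 9 as many as 40 for the slope (74). For the slope 3 of 100 splits gave as many as the real 1, with a highest other of 1. This does not exclude chance, since the slope was fitted after the graded levels of miR-330-3p, its only call, were known.

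More miRNAs were detected in non-severe asthma than in controls, by 78.5. Library depth may account for part of the difference. At 300000 reads it was 29.1 (SE 14.03, permutation p = 0.0605), under 0.5 of the 78.5 observed. The shallowest control library could not enter, and without it the difference before rarefaction was 65.4. Rarefaction lowered the number detected in both groups, to 428 in non-severe asthma and 398 in controls. Such a fall can by itself shrink a difference in numbers, so the share due to depth was not measured. Whether the set of miRNAs at countable levels was wider in non-severe asthma stays open, since at that depth 14.7 more miRNAs were expected to have 5 or more reads (SE 9.06, permutation p = 0.138, 95% interval −4.12 to 33.6). Without the shallowest control library the difference was 65.4 (permutation adjusted p = 0.0840), and among the libraries of at least 400000 reads, which leave it out as well, it was 72.2 (exact permutation adjusted p = 0.0462), while with each library left out in turn it passed in 15 of 33. The remaining 29.1 is not shown to be 0, and a biological difference in rare miRNAs between these groups stays open.

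miR-330-3p was higher in severe asthma than in controls by 2.17 (log2, 95% interval 1.15 to 3.20). Depth as the whole cause is argued against by the share of libraries expected to hold a read of it at 300000 reads, 95.9% in severe asthma, 68.0% in non-severe asthma and 33.3% in controls (exact permutation p = 0.00203 for severe asthma against controls); with depth as a covariate the fold was 2.01 (0.96 to 3.05), and the call ended because the fold was smaller and its standard error (0.52) slightly larger. With the part of the numbering, lower or higher, as a covariate the fold was 2.09 (1.07 to 3.11). This interval lies above 0, but its lower end falls just under 0.5 of the unadjusted fold, the bound asked of this test. A contribution of the numbering stays open, and a gradual trend along the numbers was not fitted. Chance stays open as well (5 of 100 splits), so that severity is one possible explanation among these for a miRNA with a median of 12 reads.

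The let-7 share was lower at higher sample numbers (r = −0.61), and no biological explanation was tested, since the labels do not say what the numbers stand for. An uneven spread of the groups over the numbers is argued against by r = −0.614 after removing the group means (permutation p = 0.00019), and depth by r = −0.664 after removing its trend (permutation p = 3e-05). Dilution by red-cell miRNAs as the whole cause is argued against by let-7a-5p relative to miR-126-3p, neither of which is on the erythroid list, with r = −0.645 (permutation p = 9e-05), and by the let-7 share of the counts outside that list, with r = −0.54 (permutation p = 0.00141; rho = −0.55, permutation p = 0.00097; r = −0.52 without the 2 farthest libraries). A part in the fall stays open, since the share was lower where the erythroid score was higher (r = −0.39, permutation p = 0.0237, adjusted p = 0.0339; rho = −0.32, permutation p = 0.0713, adjusted p = 0.0892; r = −0.31 without the 2 farthest libraries, and −0.29, −0.76 and −0.26 within controls, non-severe and severe asthma, or −0.13, −0.42 and −0.26 without the 2 farthest of each). A difference in sample handling or library preparation along the numbers may remain, and cannot be tested here without dates or batches.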
